A study of Caenorhabditis elegans with 2 samples.

How the data were processed

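Chromatin immunoprecipitation with sequencing was done on whole L1 larvae, the first larval stage of the nematode Caenorhabditis elegans. The strain was OP196, which carries an inserted transgene for eGFP-tagged SPTF-1 in an unc-119(ed3) background, per the labels. SPTF-1 is a zinc finger protein of the Sp family. The labels name the antibody only by the target, sptf-1. The 2 samples are biological replicates of 1 group, per the labels. No sample of another group and no control library was analysed here, so no comparison between conditions was made.

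The deposited files used here were lists of regions in narrowPeak format on the ce11 and ce10 genome builds, per the file records deposited with the samples. Each replicate list was derived from the alignment of that replicate and 1 further file, the same for both replicates of a build, per these records. The records do not describe that file. It was taken here to be the control alignment, because the control-normalized tracks were derived from it too and the tracks of unique reads were not. The pooled list was derived from both alignments and the same file, and the optimal IDR list from the pooled list, both replicate lists and a further file not used here, per the same records. IDR, the irreproducible discovery rate, is a measure computed from the ranks of regions in replicate lists. The aligner, the peak caller and their versions were not given in the sources used here. The deposited signal value of each region was made by the authors' peak caller from a ChIP alignment and the file taken here to be the control alignment, and its scale was not stated. The deposited −log10 q of each region, by the format's column order, was made by the same caller. In the pooled list on ce11 this column lay just below 0 for 9 regions. For some of these the value differed from 0 only by numerical rounding. For the rest it is an estimated q above 1, at most 1.07. Signal values and q values are the authors' own. Within a list, both were used to describe and rank regions, and q values to count those under 0.05. Signal values were also correlated between the replicates and matched between the builds.

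The replicate lists held 30000 regions each, described by the records as peaks and background, of which 40 in replicate 1 and 29 in replicate 2 on ce11 had a q under 0.05. All regions of a list had the same width, which was 336 bp in replicate 1, 350 bp in replicate 2 and 344 bp in the pooled and optimal IDR lists on ce11. Read depth was unknown, since the lists hold no read counts. Intervals given with shares are exact Clopper-Pearson intervals at 95% and cover counting error only. Where a share is 0, the limit that 3 counts of the total set is given beside the exact interval. Regions of a genome are not independent replicates, so p-values over regions measure these lists and not the spread between further cultures.

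Positions were compared with the WBcel235 assembly, which is ce11, and its Ensembl annotation with 46890 genes on the nuclear chromosomes. The ce10 lists were used only for counts and values, and no coordinate was converted. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and sequence copies were searched with blastn 2.17.0. Regions overlapped when they shared at least 1 bp. The top 500 regions of each replicate by signal were compared with 1000 random draws of 500 regions from the full list of replicate 2, with a one-sided permutation p. Ranks were compared over all overlapping pairs with Spearman's rho and Pearson's r of log10 signal, each with a two-sided permutation test of 100000 resamples. The share of summits within 500 bp of an annotated transcript start was set against 100000 random positions with the same chromosome proportions, by a two-sided exact binomial test. The sequence GGGCGG, the core of the GC box bound by Sp proteins, was counted on either strand within 50 bp of each summit and in windows of the same width 300 to 400 bp away, by Fisher's exact test, two-sided. Genes nearest to summits were tested against 20 gene lists by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment, on a background of 24254 genes nearest to any region of either replicate. Counts per chromosome were set against chromosome length with 100000 simulated draws. The number of regions in a window of 40 kb centred on sptf-1 and on unc-119 was given as a percentile of all windows of that size tiled along the chromosomes.

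These tests, the gene lists and the rule for named genes were fixed before the data were examined, as were the alternatives except those with regions shared in the top 5000 for starts, motif, gene lists and chromosomes and those with the pooled list for motif, gene lists and chromosomes, which were added later. The rule named every optimal IDR peak by the gene with the nearest start and the gene body holding the summit, the 10 regions with the best mean rank in both replicates outside that list, sptf-1, unc-119 and up to 4 members of any list that passed its test. No cell types were called.

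The statistics were tested on simulated data first. With 20 shared regions planted among the top 500 of 30000, the overlap test called all 20 simulations, and with 0 planted it called 1. With the motif planted in 30% of 18 windows, Fisher's exact test called 86 of 100 simulations. With 50% of 18 summits moved to a start, the exact binomial test called 78 of 100 simulations. The chromosome test made 9 calls in 200 simulations without bias.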

Results

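The data were ranked regions from ChIP of eGFP-tagged SPTF-1 in L1 larvae, as 2 replicate lists of peaks and background, 1 pooled list and 1 list of optimal IDR peaks. The optimal IDR list on ce11 held 18 peaks, and the pooled list held 193 regions. The 18 peaks were the 18 regions of highest signal in the pooled list. On ce10 the optimal IDR list held 11 peaks, all of which matched a ce11 peak of the same chromosome within 0.01 signal units, and the pooled list again held 193.

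The highest optimal IDR peak lay on chromosome I at 933303 to 933646, in intergenic sequence 5008 bp upstream of nas-30 (WBGene00003548), a gene for an astacin-type metalloprotease, with a signal of 57.3. The other 17 peaks lay close together in signal, between 35.1 and 40.4. A peak on chromosome III at 13778807 to 13779150, 1236 bp upstream of pot-3 (WBGene00007065), a gene of the POT1 family of telomere-binding proteins, ranked 1 in both replicates. Its signal was 38.0 in the pooled data, 37.1 in replicate 1 and 26.5 in replicate 2, and its summit lay 4822 bp from the end of the chromosome. A peak in an intron of mnk-1 (WBGene00011304), which encodes a MAP kinase-interacting kinase, lay on chromosome II at 10550379 to 10550722 with a signal of 39.7.

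Chromosome V held 7 of the 18 peaks. Among these, a peak at 18722538 to 18722881 lay in an intron of the pseudogene Y17D7C.3 (WBGene00045366) with a signal of 40.4, and a peak at 18714430 to 18714773 lay in an exon of the neighbouring pseudogene Y17D7C.4 (WBGene00050903) with a signal of 39.1. A second neighbouring pair lay at 19634219 to 19634562, in an intron of Y43F8C.6 nearest to the start of Y43F8C.5, with a signal of 39.1, and at 19630133 to 19630476, in an intron of dyf-19 nearest to the pseudogene Y43F8C.t3, with a signal of 35.7. The remaining peaks of the chromosome lay in coding sequence of C14A6.6 at 18165339 to 18165682 (signal 37.1, nearest start C14A6.5), 3056 bp upstream of the ligand-gated ion channel gene lgc-26 at 265079 to 265422 (signal 36.7), and in an intron of the chemoreceptor pseudogene srw-75 at 16634836 to 16635179 (signal 36.2).

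On chromosome III, peaks lay 557 bp upstream of lelo-2 at 1427611 to 1427954 (signal 38.1), in an intron of Y50D7A.1 at 312915 to 313258 (signal 36.1, nearest start Y50D7A.10), and 4640 bp upstream of the noncoding RNA gene C48D5.9 at 3562110 to 3562453 (signal 35.1). The peak at 12250176 to 12250519 on the same chromosome lay 117 bp upstream of sls-2.8 (WBGene00004840), an SL2 spliced leader RNA gene, and 184 bp from a start of tim-1, with a signal of 36.3. On chromosome X, a peak at 14950973 to 14951316 lay in the 3′ UTR of pag-3, a zinc finger gene of neuronal fate, nearest to the start of the noncoding RNA gene F45B8.6 (signal 38.2). A peak at 593649 to 593992 lay 139 bp upstream of F13C5.2 (signal 35.7). The other peaks lay in coding sequence of M28.4 on chromosome II at 10645843 to 10646186 (signal 37.4, nearest start M28.10) and in coding sequence of Y44E3A.1 on chromosome I at 3339569 to 3339912 (signal 35.7).

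Of the 18 summits, 7 were intergenic, 6 lay in introns, 3 in coding sequence, 1 in a 3′ UTR and 1 in an exon of a pseudogene. The nearest start belonged to a protein-coding gene for 11 peaks and to a pseudogene for 4. The lowest q among the 18 peaks was 0.0667, shared by 8 of them, and the highest was 0.486, so that 0 of the 18 had a q under 0.05 in the deposited list.

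The first comparison asked whether the replicates ranked the same places highest. The peaks near pot-3, mnk-1, Y17D7C.3, M28.10 and lelo-2 were among the top 500 regions of both replicates. The peak near nas-30 ranked 3 in replicate 1 and 13016 in replicate 2, and that near C14A6.5 ranked 25 and 18103. In the other direction, the peak near Y50D7A.10 ranked 2074 in replicate 1 and 2 in replicate 2. The peaks at Y17D7C.4 and Y44E3A.1, which ranked 2 and 5 in replicate 1, overlapped no region of replicate 2. A place in the optimal IDR list therefore did not by itself mean agreement between the ranks of the replicates. In all, 15 of the 18 peaks overlapped a top 500 region of replicate 1, 8 a top 500 region of replicate 2 and 5 both. Of the 16 peaks in both lists, 9 ranked higher in replicate 1, 6 in replicate 2 and 1 was tied (exact sign test, two-sided, p = 0.607). This test leaves out the peaks at Y17D7C.4 and Y44E3A.1 and the size of the rank gaps. The median rank was 21.5 in replicate 1 over the 18 peaks and 462 in replicate 2 over the 16 found there. A q under 0.05 was listed for 40 regions of replicate 1 and 29 of replicate 2. Of the optimal IDR peaks, 10 had one in replicate 1, 3 in replicate 2 and only that near pot-3 in both.

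**Figure D1:**
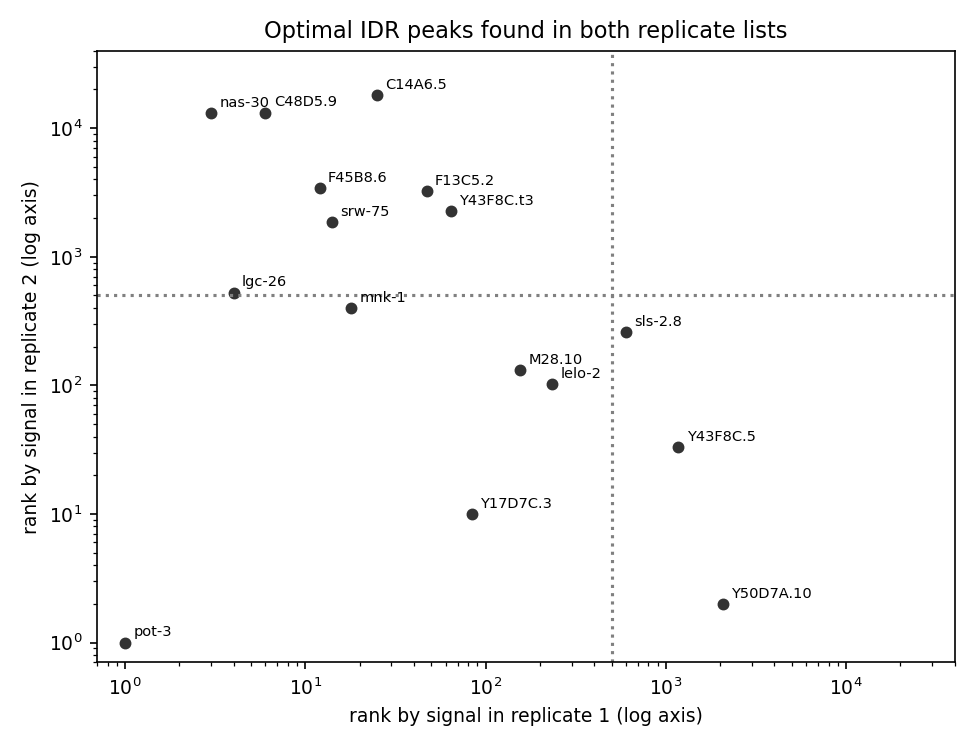
Rank by signal in replicate 1 (x axis) and replicate 2 (y axis), both log axes, of the 16 optimal IDR peaks found in both replicate lists, each named by the gene with the nearest start, with dotted lines at rank 500. The peak near pot-3 ranked 1 in both, and 5 of the peaks lay within rank 500 on both axes.

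Of the top 500 regions of replicate 1, 8 overlapped a top 500 region of replicate 2, which is 1.6% (95% exact interval 0.693 to 3.13%). Random draws gave a mean of 3.35 (one-sided permutation p = 0.022). Both lists were derived from the same file, taken to be the control, which the draws do not account for, so part of the excess may come from it. The call was lost with reciprocal overlap of 50%, at 5 regions or 1% against a mean of 2.2 in random draws (permutation p = 0.0739), and with the top 1000, at 18 regions or 1.8% against 12.3 (permutation p = 0.0719). It held with summits within 100 bp, at 5 regions against 1.64 (permutation p = 0.022), and with the top 100, at 3 against 0.17 (permutation p = 0.004). Among the top 5000, 326 regions overlapped against a mean of 278.5 in random draws (permutation p = 0.002). The regions of the top 500 shared outside the optimal IDR list lay near F19D8.5, ubql-1 and T26E3.6.

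**Figure D2:**
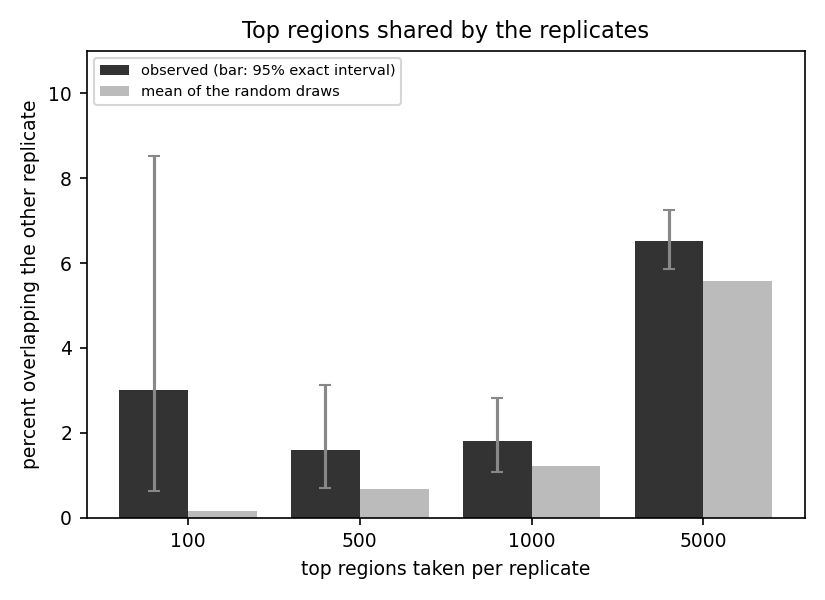
Percent of the top regions of replicate 1 that overlapped a top region of replicate 2 (y axis) by the number of top regions taken per replicate (x axis), with 95% exact intervals, beside the mean of 1000 random draws. The observed share was 1.6% for the top 500 and 6.52% for the top 5000, where the draws gave 5.57%.

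The full lists overlapped at 8377 regions of replicate 1, which is 27.9% of that list. Across these pairs of regions, which are not independent replicates, Spearman's rho of the signals was 0.0215 (permutation p = 0.0487) and Pearson's r of log10 signal was 0.0307 (permutation p = 0.00486). The permutation does not account for the shared file either, so part of the correlation may come from it. Spearman's rho lost its call with reciprocal overlap of 50% (rho 0.0238, permutation p = 0.0805) and with summits within 100 bp (rho 0.0258, permutation p = 0.114). Pearson's r kept its call in both, at 0.0299 (permutation p = 0.0287) and 0.034 (permutation p = 0.0366).

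Of the 10 regions with the best mean rank outside the optimal IDR list, 4 lay within 500 bp of a start, where 31.5% of random positions and 34.8 and 35.2% of all regions of replicates 1 and 2 did. The first, on chromosome X at 13823458 to 13823793, lay 7 bp upstream of the noncoding RNA gene F19D8.5 and 44 bp from a start of twk-23, a potassium channel gene, and ranked 87 and 81 in replicates 1 and 2. A region on chromosome I at 7021752 to 7022087 lay 52 bp upstream of ubql-1, which encodes ubiquilin, and ranked 213 and 411. A region in coding sequence of T26E3.6 on chromosome I at 12661212 to 12661547, 126 bp downstream of its start, ranked 468 and 153. A region in coding sequence of rpl-3, a ribosomal protein gene, on chromosome III at 3868464 to 3868799, ranked 142 and 816. The others lay nearest to Y39B6A.81, frpr-7, linc-94, sra-34, Y17D7C.7 and srw-48. Of these, frpr-7, sra-34 and srw-48 encode predicted G protein-coupled receptors, and Y17D7C.7 lies at the same cluster on chromosome V as the peaks in Y17D7C.3 and Y17D7C.4. The regions near F19D8.5, ubql-1, linc-94, Y17D7C.7 and srw-48 were not in the pooled list, and the others were.

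The next comparison asked whether peaks lay near gene starts. The peaks nearest to a start were those at Y44E3A.1 (114 bp), sls-2.8 (117 bp), F13C5.2 (139 bp) and Y43F8C.t3 (477 bp). These 4 of 18 summits within 500 bp made 22.2% (95% exact interval 6.41 to 47.6%), against 31.3% of random positions (exact binomial test, two-sided, p = 0.612). Starts of all annotated genes were counted, including noncoding RNA genes and pseudogenes. With protein-coding starts only, 3 of 18 summits lay within 500 bp, 16.7%, against 24.0% of random positions (exact binomial p = 0.59). Of the 8 shared regions of the top 500, 3 lay within 500 bp of a start, which is 37.5% (95% exact interval 8.52 to 75.5%; exact binomial p = 0.704). The pooled list had 55 of 193 summits within 500 bp, 28.5%, against 33.9% of random positions (exact binomial p = 0.128). The share was 37.6% in the top 500 of replicate 2 alone (exact binomial p = 0.052) and 35.2% in that of replicate 1 alone (exact binomial p = 0.672).

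GGGCGG was found at the summits near sls-2.8 and C48D5.9 and at no other optimal IDR peak. These 2 of 18 windows made 11.1% (95% exact interval 1.38 to 34.7%), against 0 of 36 flanking windows (Fisher's exact test, two-sided, p = 0.107). Against top regions of replicate 1 that replicate 2 lacked, of which 5 of 314 had the sequence, the difference passed the threshold (Fisher's exact p = 0.0496). With 100 bp on either side it was 2 of 18 windows against 2 of 36 (Fisher's exact p = 0.594), and of the other sequences of the same composition GCGGGG and GGCGGG were found in 5.56% of the 18 windows each. The KLF-type sequence GGGTGTG and the longer GGGGCGGGG were found in 0 of 18 windows each (95% exact interval 0 to 18.5%), where 3 counts of 18 allow a share of up to 16.7%. Among the 8 shared regions of the top 500, 0 windows had GGGCGG (95% exact interval 0 to 36.9%), where 3 counts of 8 allow a share of up to 37.5%. With the top 500 regions of replicate 2 alone the share was 2.4%, against 1.5% of flanking windows (Fisher's exact p = 0.222), and with those of replicate 1 alone 1.8%, against 1.4% (Fisher's exact p = 0.656).

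Of the 20 gene lists, only that of snoRNA and snRNA genes had a member nearest to an optimal IDR peak, sls-2.8. By Fisher's exact test with Benjamini-Hochberg adjustment, 0 lists passed an adjusted p of 0.05, and 0 had an unadjusted p under 0.05. The lists of Sp/KLF factors, Wnt pathway, ribosomal proteins, histones, collagens and cuticle, nuclear hormone receptors, homeobox and bHLH factors, epidermal regulators, body wall muscle, pharynx, intestine, neurons, glia and excretory system, germline, chaperones, oxidative phosphorylation, tRNA and microRNA genes had 0 members there. With 18 genes near peaks, the expected count per list was low, from 0.00297 for Sp/KLF factors to 0.207 for tRNA genes. Counts of 0 therefore do not speak against any list.

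By chromosome, 7 of the 18 peaks lay on V, 5 on III, 2 each on I, II and X, and 0 on IV. Chromosome length gave 3.76 on V, 2.47 on III and 3.14 on IV, and the departure from it did not pass the test (chi-square 9.34, p = 0.0899 from 100000 simulated draws). The ce10 list had 4 peaks on V, 3 on III, 2 on II, 1 each on I and X and 0 on IV.

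The last comparison looked at the genes tied to the transgene. The sptf-1 gene (WBGene00009743) lies on chromosome I at 10366621 to 10371697, and the window of 40 kb around it held 3 listed regions in replicate 1 and 1 in replicate 2, against a median of 12 in each. These counts were at percentiles 0.879 and 0.439 of 2503 windows. No listed region of either replicate lay in the gene. The unc-119 gene (WBGene00006843), the marker mutated in the strain, lies on chromosome III at 10902641 to 10908935, and its window held 20 regions in replicate 1 and 18 in replicate 2, at percentiles 97.9 and 94.5. Neither window held a region of the pooled list. The highest signal in the sptf-1 window was at percentile 56.3 in replicate 1, from a region 18042 bp from the centre of the gene, and at percentile 2.04 in replicate 2.

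**Figure D3:**
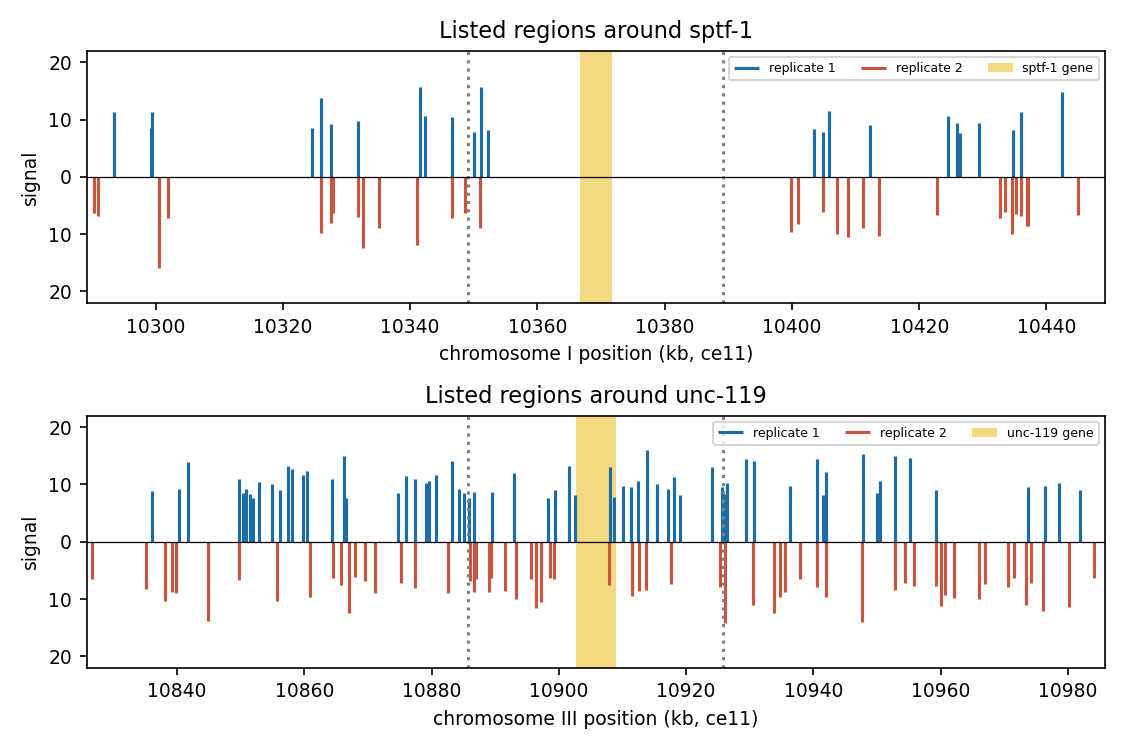
Listed regions around sptf-1 and unc-119, by position in kb on ce11 (x axis) and the deposited signal (y axis), with replicate 1 drawn upward and replicate 2 downward, the gene shaded and dotted lines at the edges of the window of 40 kb. The sptf-1 window held 3 and 1 regions and the unc-119 window 20 and 18.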

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

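The sets from the top 5000 of both replicates and the pooled list for motif, gene lists and chromosomes were chosen after seeing the data, and all other alternatives before. Of 70 alternatives, 48 kept the direction and the side of the threshold, or a count within 1.5 times. Some of these could hardly change, so the tally does not measure robustness. Leaving out mitochondrial peaks altered no value, few gene list members were expected near peaks, and locus percentiles with a replicate left out repeat those of the other. The optimal IDR list fell to 11 peaks on ce10, 1 of them on X against 2, and to 9 by construction when only the higher part by signal was kept. The overlap of the top 500 lost its call at 1% with reciprocal overlap and at 1.8% with the top 1000. Spearman's rho lost its call at 0.0238 with reciprocal overlap and 0.0258 with summits within 100 bp. Among pairs with a top 1000 member it was −0.672, but random pairing followed by the same selection gave −0.719 (95% range −0.747 to −0.692), so the sign comes from the selection. The observed value lay above that range, and the random pairing does not account for the shared file. The share near a start passed no test, and it lay above random at 16.7% within 200 bp, 37.5% in the shared top 500, 37.7% in the shared top 5000, and 35.2 to 37.6% when either replicate was left out. GGGCGG passed the threshold at 11.1% against unshared top regions, a background not kept separate from the peaks. It also passed at 3.63% in the pooled list, and fell below its flanks at 0.613% in the shared top 5000. With either replicate left out it was 1.8 to 2.4%, and neither passed. The sptf-1 percentile in replicate 1 was 56.3 by highest signal. The unc-119 percentile in replicate 1 was 96.9 in 20 kb, 96.7 by summed signal and 59.7 by highest signal. In replicate 2 it was 79.6 in 20 kb, 89.5 by summed signal and 26.8 by highest signal. With both replicates together it was 98.5, and 94.5 to 97.9 with either left out. Except for the selection and the shortened list, the cause was not tested. The ce10 counts per chromosome have no test, since ce10 lengths were not used here. No paired analysis was possible because there is 1 group. Depth was unknown, and 18 peaks limit every share to wide intervals.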

Other observations

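The comparisons in this part of the pooled list, of chromosome ends and of the stretch around sptf-1, and the tests of weak enrichment and of transgene copies, were chosen only after the results were seen. In the pooled list, GGGCGG lay at 7 of 193 summits, 3.63% (95% exact interval 1.47 to 7.33%), against 2 of 386 flanking windows, 0.518% (Fisher's exact p = 0.00784). In the shared top 5000 it lay at 2 of 326 summits, 0.613%, below the 1.23% of flanking windows (Fisher's exact p = 0.51). The flanking share of the pooled list was below the 1.4 and 1.5% of flanks in the top 500 of replicates 1 and 2, where the test did not pass. Beside sls-2.8 and C48D5.9, the summits with the sequence lay nearest to npr-26, scl-23, Y53H1C.8, miz-1 and vamp-7. The genes nearest to pooled regions included the ribosomal protein genes rps-26, rpl-3 and rpl-35, 3 against 0.38 by chance (Fisher's exact p = 0.0065, Benjamini-Hochberg adjusted p = 0.13), and the nuclear hormone receptor genes nhr-107, nhr-61, nhr-71, nhr-178 and nhr-49, 5 of the 240 list members in the background (p = 0.0395 by Fisher's exact test, Benjamini-Hochberg adjusted p = 0.395). A region 9 bp from a start of glh-2, a germline helicase gene, had a pooled signal of 31.3.

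Many optimal IDR peaks lay toward chromosome ends. Of the 18 summits, 15 lay outside the central 50% of their chromosome, which is 83.3% (95% exact interval 58.6 to 96.4%; exact binomial p = 0.00754). The test counts each summit as independent, though the neighbouring pairs at Y17D7C and Y43F8C on chromosome V are among the 15, so the p-value is too low. The share outside the central 50% was 64.2% in the pooled list, which held further regions at the Y17D7C cluster. It was 55.2% in the top 500 of replicate 1 (exact binomial p = 0.0225) and 52.6% in that of replicate 2 (exact binomial p = 0.264). All listed regions gave 52.1% in replicate 1 and 51.7% in replicate 2. The median share of soft-masked bases in the 18 peaks was 44.5%, against 31.0% in random sets, whose central 95% reached from 19.2 to 45.8%.

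Properties of the optimal IDR peaks were tested for a possible distance from annotated starts. That distance was not shown: the share of summits within 500 bp passed no test, and the median distance was 967.5 bp against 909 bp for random positions. The values are given as descriptions only. Near-identical copies elsewhere were found for 11.1% of the peaks, those near nas-30 and lgc-26, against 12.9% of random windows (exact binomial p = 1). The median GC content was 35.8%, within the central 50% of random sets, 34.2 to 36.5%, and any of GGGCGG, GGGTGTG and GGGGCGGGG was found at 11.1% of summits (95% exact interval 1.38 to 34.7%).

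Few of the top 500 regions were shared by the replicates. Different base composition of the libraries' top regions is a candidate explanation. The median GC content of the top 500 in replicate 1 lay below that in replicate 2, a difference of −2.02 percentage points (permutation p = 1e-05, the smallest the resamples can give). GC content was measured on the reference sequence of the listed regions and not on reads. Random splits of the same regions into 2 sets, each region taken as independent, gave no difference this large, so small overlap alone does not account for it. Whether base composition lowered the overlap, or both follow from another difference between the lists, was not tested. The bound set beforehand was 2 points, and the bootstrap interval, −3.02 to −1.29, reached past it on both sides. Weak enrichment over background stays open: the highest share of a top 500 with a q under 0.05 was 8%, but with 40 and 29 such regions in the whole lists it was bound to be low, so it decides nothing. No biological explanation was tested, since the replicates share a group.

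The stretch of chromosome I without a listed region in either replicate around sptf-1 reached from 10352322 to 10399638. At 47317 bp it was number 6 by length of 49176 such stretches, whose median was 1095 bp, and it held 9 protein-coding genes, among them sptf-1, ned-8, cox-19 and mgl-2, with 29.8% soft-masked bases and 0 unknown bases. A number of listed regions raised by extra transgene copies was not seen at sptf-1, whose percentile was at most 0.879 in the window of 40 kb and 1.92 in that of 80 kb. The question stays open at unc-119, at percentiles 97.9 and 94.5 in 40 kb and 96.9 and 79.6 in 20 kb in replicates 1 and 2. Whether extra copies in the control lower the number is not decided at unc-119 by these percentiles, and at sptf-1 it stays an untested possibility, since the low count itself raised the question and the control and the extent of the transgene were not analysed here. Longer stretches without regions occurred elsewhere, the longest with 140660 bp on chromosome V.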
